A study of Mus musculus with 24 samples.

How the data were processed

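Per the labels' protocols, forebrain was taken after the olfactory bulb, cerebellum and brainstem were removed, RNA was isolated with TRIzol and cleaned on columns, and biotin-labelled cRNA made by in vitro transcription was hybridised to Affymetrix mouse arrays. The deposited values were used as log2 signals without a further transformation; lowest values per array were 2.07 to 2.19, highest 13.3 to 13.7 and medians 4.28 to 4.38. The normalization method is not given in the sources used here. The medians are near-equal, but whether the authors scaled, centred or quantile-normalized them stays unknown. All 24 columns were mapped to genotype, age and replicate number from the labels, and 0 were left over.

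The table held 45101 probe sets, of which 64 were array controls. Of the other 45037, 34945 carried 1 gene symbol, 932 several and 9160 none in the annotation used here. For each gene the probe set with the highest mean over all arrays was taken, leaving 18193 genes. C4b was not analysed here, and 1 further gene of the fixed set is not reported here. The number of mice per group, 4, limits precision; the median standard error of a genotype difference at 1 age was 0.0977 log2.

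All arrays entered 1 limma fit with the 6 groups as means (18 residual and 7.47 prior degrees of freedom), and contrasts gave the genotype difference at each age, its mean over 3 ages and over days 70 and 80, its change between ages, and age differences within genotype. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Gene groups were 43 lists fixed by name, with 7 to 40 measured members (median 21; 850 of 926 members measured), tested by camera with an inter-gene correlation of 0.01 and again with a correlation estimated from the data. Per-array means were compared by exact permutation of the 8 arrays, where 0.0286 is the smallest p possible. The comparisons, gene lists, thresholds, naming rule and most alternatives were written before the data were examined.

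Named genes follow a rule: for each comparison the 10 largest rises and 10 largest falls that passed; where fewer than 5 passed, also the 5 smallest p as not passing; up to 4 members of each list that passed, or the first members where none did; and a fixed set of APP, glial and activity genes. Genes outside the rule were chosen after the values were seen: the day 150 genes beyond the first 10, the values of Vim, Mpeg1, Lyz1, Rims1 and the myelin genes at other ages, the genes gained when an array was left out, and all genes near Prmt3. Positions of genes were taken from the GRCm38.p6 gene table and served to tell which genes lie on the same chromosome and, for Prmt3, to order the measured genes along it.

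The pipeline was tested on simulated arrays in which each gene had the mean and SD of the real values. Of 100 genes shifted by 0.5 log2, 78% passed, and of 100 shifted by 1, 99% passed. There were 9 false calls among 186, and 0 false calls arose at day 70. The simulated genes varied independently, without structure shared between genes. More of them were changed than passed in any real comparison, which eases the adjusted threshold. Recovery in the real data can therefore be lower. Alternatives tried were quantile normalization, median centring, leaving out the dimmest 40% of genes, the mean of all probe sets of a gene, all probe sets, empirical Bayes with trend and robust settings, array weights, replicate number as block, Xist as covariate, an adjusted p under 0.10, only the arrays compared, and leaving out each array in turn. Leaving out both day 80 arrays numbered 1, the first principal component as covariate and 2 other forms of the mean of the 22 genes were added after the data were seen. Pseudocount alternatives were not run because the values were already log2. Chance was examined by splitting the same arrays into groups in all 35 ways, or by 100 labellings, the real one included and the rest random.

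Versions were R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.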

Results

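Forebrain RNA of TgCRND8 mice, which carry a human APP transgene with the Swedish and Indiana mutations and develop amyloid deposits as they age, was compared with that of littermate controls at 70, 80 and 150 days of age. Each genotype and age had 4 mice and 1 array per mouse, 24 arrays in all. The deposited values were log2 signals with array medians between 4.28 and 4.38, and 18193 genes were tested. Correlations between arrays were as high across groups (median 0.9954) as within them (median 0.9957).

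No probe set of the mouse App gene passed between genotypes at any age by limma: the brightest read 11.9 in both genotypes at day 150, a difference of -0.01 log2 (adjusted p = 0.999 by limma with Benjamini-Hochberg adjustment, n = 4 per group). A second bright App probe set was higher by 0.17 at day 150 (exact permutation p = 0.229) and a dim one by 0.13 (2.81 against 2.68; exact permutation p = 0.0286). Whether the mouse probe sets for App and Prnp, the gene whose promoter drives many such transgenes, bind the RNA of the transgene is not known from the labels, so these genes cannot check the genotype labels. Xist, the RNA that coats the inactive X chromosome of females, was high in 19 arrays and low in 5. The low arrays were 1 control of day 70, 2 controls of day 80 and 2 TgCRND8 of day 80. Adding the Xist level to the model left all 22 of the day 150 genes given next past the threshold. No day 150 array had low Xist, so this covariate could hardly have moved the day 150 differences.

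At day 150, genes of activated microglia and reactive astrocytes were higher in TgCRND8 forebrain. Cst7, the cystatin F gene of microglia around plaques, rose by 1.59 log2 (standard error 0.105; mean 4.55 with SD 0.30 against 2.96 with SD 0.067), and Gfap, the intermediate filament of reactive astrocytes, rose by 1.42 (standard error 0.141; 8.56 against 7.15). Tyrobp, the signalling partner of the lipid receptor Trem2, rose by 1.31 (7.01 to 8.32) and Trem2 itself by 0.62 (4.83 to 5.45). Genes of phagocytes rose with them: Cd52 by 1.05, Cd68 by 0.999, Mpeg1 by 0.84 and Ptprc by 0.71. The lysozyme gene Lyz1 rose by 1.01. Vim, a second astrocyte filament gene, rose by 0.74 and Ctsc, a lysosomal protease gene, by 0.71. By limma with Benjamini-Hochberg adjustment, n = 4 per group, 22 genes rose and 0 fell; adjusted p was 5.49e-10 for Cst7, 2.14e-06 for Gfap, 0.00076 for Tyrobp and 0.0326 for Trem2. At unadjusted p under 0.05 there were 796 genes, 4.38% of those tested. The control level of Cst7 lay below the lower quartile of every array (3.15 to 3.32), so the size of its rise is uncertain. For each of the 22 genes all 4 TgCRND8 arrays lay above all 4 control arrays.

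The other 11 of the 22 included C1qa (0.54 log2) and C1qc (0.69), which code for chains of the complement starter C1q. They also included the cathepsin genes Ctss (0.56), Ctse (0.52), Ctsz (0.48) and Ctsd (0.36). Osmr, the oncostatin M receptor gene, rose by 0.65, Cyba, a subunit of the phagocyte oxidase, by 0.50, Cd9 by 0.46 and Tmem176b by 0.43. Rims1, a scaffold of the presynaptic release site, was the neuronal member. It was higher by 0.49 (9.35 against 8.86), adjusted p = 0.00762 by limma with Benjamini-Hochberg adjustment. In TgCRND8 it read 9.35 at day 70 too, while controls read 9 at day 70. Control means of day 150 also lay below those of day 70 for Cd9 (7.94 against 8.18) and Cd68 (4.45 against 4.81), among others. For Ctss, Ctse, Trem2 and Mpeg1 they lay above. Clec7a (0.36, adjusted p = 0.687 by limma), Itgax (0.33, 0.546) and Serpina3n (0.29, 0.182), also known from plaque-associated glia, did not pass, nor did Apoe (0.03, 0.999). With control array number 2 of day 150 left out 12 genes passed, and 12 of the 22 genes passed in all 8 fits with 1 array left out. Trem2 and Ctsd passed in only 2 of the 8, and Cd52, Ctse and Cyba in 1. Second, dimmer probe sets differed by -0.07 for Trem2, -0.12 for Ctse, -0.18 for Ptprc and -0.06 and 0.03 for Osmr. Those of Ctsc differed by 0.13 and 0.07, and those of Lyz1 by 0.85 and 0.18. Second probe sets of Gfap, Vim, Ctsz and Rims1 were higher as well.

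**Figure D1:**
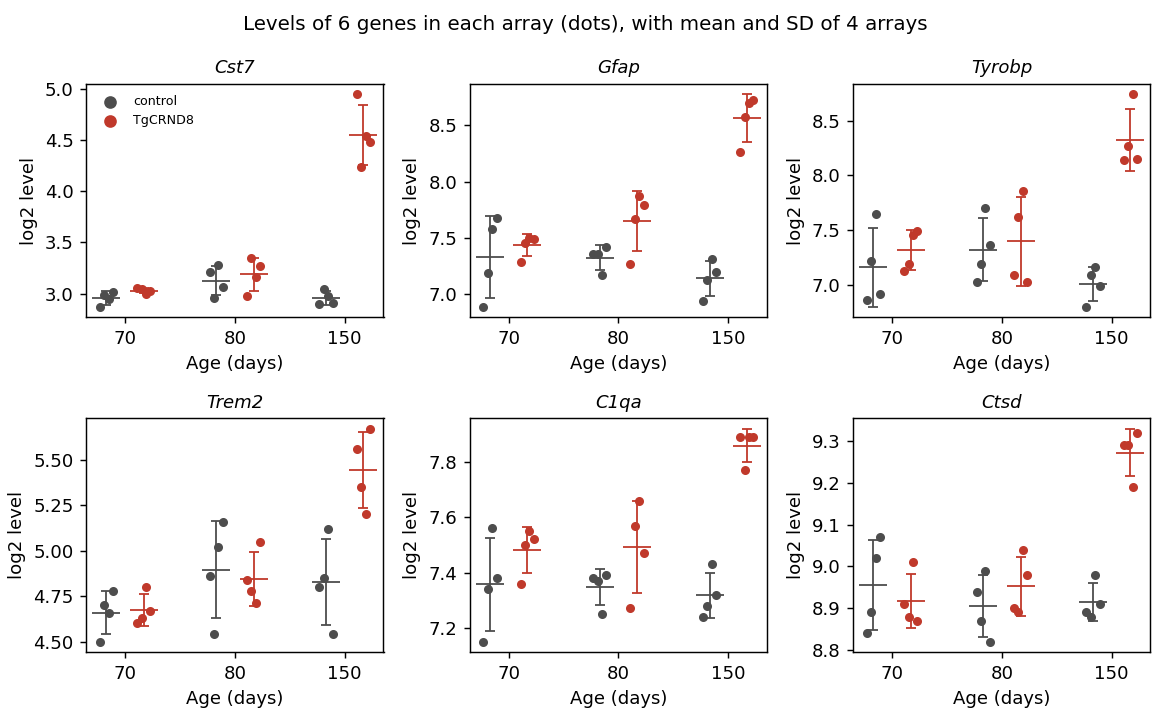
Log2 signal of Cst7, Gfap, Tyrobp, Trem2, C1qa and Ctsd by genotype and age. Dots are arrays, 4 per group; bars give the mean and SD.

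At day 150 groups of genes of microglia, lysosomes and cholesterol synthesis were higher in TgCRND8. Of 32 measured genes of plaque-associated microglia, 29 were higher and 3 lower, with a median difference of 0.18 log2; 8 rose and 24 did not pass, and 12 passed when adjusted over the list alone. Lysosome genes, which clear engulfed material, were higher for 30 of 36 (median 0.14; 5 rose, among them Ctss and Ctsd, and 31 did not pass). Complement genes were higher for 14 of 19 (median 0.10; C1qa and C1qc rose, 17 did not pass), homeostatic microglia genes for 17 of 22 (median 0.12; 1 rose, 21 did not pass) and reactive astrocyte genes for 19 of 30 (median 0.048; Gfap, Vim and Osmr rose, 27 did not pass). All 20 cholesterol synthesis genes were higher by a median of 0.19, including Hmgcs1 (0.32), Sqle (0.28) and Idi1 (0.19); none passed over all genes, 796 of all genes had unadjusted p under 0.05, and 6 of the 20 passed by limma when adjusted over the list alone. Camera, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment, gave adjusted p = 1.63e-28 for plaque-associated microglia, 5.81e-15 for lysosome, 4.55e-14 for cholesterol synthesis, 1.39e-06 for complement and for homeostatic microglia, and 1.46e-06 for reactive astrocytes. With an estimated correlation these 6 groups held (adjusted p from 4.64e-06 to 0.01 by camera). Lists share members, here and in the other comparisons, so their results are not independent. Ctsd, Ctsz and Cd68 are in both the plaque-associated microglia and the lysosome list, and Itgam is in both the homeostatic microglia and the complement list. Relative to all arrays, the cholesterol synthesis mean was -0.217 to -0.125 in day 150 controls and -0.0114 to 0.0782 in day 150 TgCRND8. Controls of day 70 read -0.0226 to 0.124. The cholesterol difference thus came with low day 150 controls, not with TgCRND8 levels above those of younger controls.

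Across all comparisons the list calls that held with an estimated correlation were these 6 at day 150, 6 for the mean over ages, 2 for the day 150 change of the genotype effect, 2 for age in controls and 6 for age in TgCRND8. At day 150 antigen presentation genes (15 of 19 higher; adjusted p = 9.35e-05 by camera) did not hold, adjusted p = 0.0762 with an estimated correlation. Genes at late-onset Alzheimer risk loci (19 of 31 higher, of which Trem2 rose; adjusted p = 0.00882 by camera) had adjusted p = 0.102 with an estimated correlation. Lymphocyte genes (11 of 14 lower; adjusted p = 0.00882 by camera) had adjusted p = 0.382 with an estimated correlation, and meninges and fibroblast genes (14 of 19 lower; 0.0392) had adjusted p = 0.54 with an estimated correlation.

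No gene of the excitatory neuron, inhibitory neuron, resting astrocyte or myelin groups passed at day 150. The glutamate transporter gene Slc17a7 differed by 0.03 log2, Camk2a by 0.04, Gad1 by -0.13 and Gad2 by 0.01, and medians were 0.016 for 22 excitatory neuron genes and 0.013 for 18 inhibitory neuron genes. Genes of resting astrocytes, such as Aldoc (0.00) and Slc1a3 (-0.02), had a median of -0.002 over 21 genes beside the rise of Gfap. Oligodendrocyte and myelin genes had a median of -0.024 over 21 genes (Mbp -0.07, Mog 0.12), and 23 APP processing genes had a median of 0.032. Adjusted p by camera was 0.723, 0.874, 0.376, 0.874 and 0.463 for these 5 groups in that order.

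**Figure D2:**
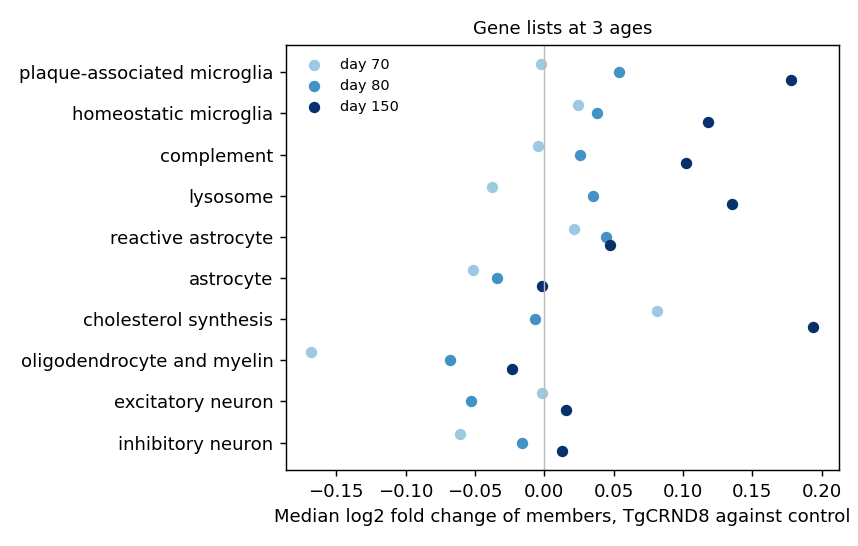
Median log2 difference between TgCRND8 and control for 10 gene groups at days 70, 80 and 150 (4 arrays per group and age).

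At day 70, 20 of 21 oligodendrocyte and myelin genes were lower in TgCRND8, but no single gene passed, and the group passed camera only with the preset correlation (adjusted p = 5.17e-10; adjusted p = 0.0713 with an estimated correlation). The median difference was -0.17 log2: Mag was lower by 0.35, Mog by 0.21 and Mbp by 0.09, each with 4 arrays per group. Neuronal activity genes were lower in 20 of 30 (Arc by 0.60, Fos by 0.59), and genes of the unfolded protein response, which protects the endoplasmic reticulum, in 20 of 26 (Hspa5 by 0.29). Heat shock genes were lower in 16 of 18 and glucocorticoid response genes in 12 of 19, while 14 of 20 cholesterol synthesis genes were higher. For activity-regulated genes camera gave adjusted p = 0.00267, or adjusted p = 0.643 with an estimated correlation, and for the unfolded protein response 0.000611, or adjusted p = 0.36 with an estimated correlation. Heat shock, cholesterol synthesis and glucocorticoid genes each had adjusted p = 0.0039 by camera, or adjusted p = 0.643, 0.643 and 0.36 with an estimated correlation. Heat shock genes rested on control array number 4 of day 70, the only array of that age with low Xist, without which their adjusted p by camera was 0.456. Without TgCRND8 array number 2 of day 70, Fos differed by -0.32. Over the list alone 3 myelin genes passed by limma.

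Among single genes at day 70, Prmt3, an arginine methyltransferase gene, had the smallest p: it was lower by 0.81 log2 (standard error 0.161; 5.92 against 6.73, n = 4 per group; adjusted p = 0.653 by limma with Benjamini-Hochberg adjustment). Slc7a2 followed with -0.33 and 1700034H15Rik with 0.31 (adjusted p = 0.977 each by limma), then Gas2l2 (0.40) and Efhd1 (-0.45). Gfap differed by 0.10. By limma 0 genes passed; 591 genes, 3.25% of those tested, had unadjusted p under 0.05, and camera passed 8 lists with the preset correlation and 0 with an estimated one.

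At day 80 none of the 22 genes of day 150 passed. Gfap was higher by 0.32 log2 (7.65 against 7.33), Vim by 0.30, Mpeg1 by 0.33 and Lyz1 by 0.42, with 4 arrays per group, the larger differences among them, while Cst7 differed by 0.06, Trem2 by -0.05 and Ptprc by -0.07. The smallest p belonged to Teddm2 (0.42; adjusted p = 0.973 by limma with Benjamini-Hochberg adjustment), Acsm1 (0.35), Syce1 (0.39), Ppp1r12c (-0.29) and Gm29805 (0.34). By limma 0 genes passed and 685, or 3.77%, had unadjusted p under 0.05. Camera passed 1 list, blood genes, 7 of 9 higher with Alas2 at 1.04 (adjusted p = 0.00212; adjusted p = 0.142 with an estimated correlation). Over the list alone 3 blood genes passed by limma. The haemoglobin genes Hba-a1 (-0.05) and Hba-a2 (0.17) were dim, at 2.72 and 3.21 in TgCRND8 of day 150. That is below or within the range of the arrays' lower quartiles (3.15 to 3.32), so they cannot show whether blood content differed. With TgCRND8 array number 1 left out 2 genes passed, Neurl1b at -0.63 (adjusted p = 0.0071 by limma) and Tgif1 at 0.49 (adjusted p = 0.0233 by limma).

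The mean of days 70 and 80 was taken to look for early differences. Gfap was higher by 0.21 log2, Vim by 0.20, Mpeg1 by 0.24 and C1qa by 0.13, while Arc was lower by 0.39 and Fos by 0.34 (8 arrays per genotype; adjusted p = 0.999 for each by limma with Benjamini-Hochberg adjustment). By limma 0 genes passed, 767 had unadjusted p under 0.05, and camera passed 9 lists, of which 0 held with an estimated correlation. The largest was oligodendrocyte and myelin genes with a median of -0.11 (adjusted p = 1.16e-07 by camera; adjusted p = 0.195 with an estimated correlation). With TgCRND8 array number 1 of day 80 left out, Prmt3 passed at -0.64 (adjusted p = 0.0225 by limma).

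The 22 genes of day 150 were averaged for each array to ask whether they had begun to move earlier, a test chosen after the day 150 values were seen. At day 70 the mean was 0.0782 higher in TgCRND8 (0.155 against 0.0772 above the day 150 controls; exact permutation p = 0.229, n = 4 per group), with 18 of the 22 genes higher. At day 80 it was 0.128 higher (0.201 against 0.0726; exact permutation p = 0.114), with 17 of the 22 higher and 3 of 4 TgCRND8 arrays above all controls. At day 150, where the genes were picked, the difference was 0.758. Whether Gfap, Cst7 and their companions had begun to move by day 80 stays open with 4 arrays per group.

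**Figure D3:**
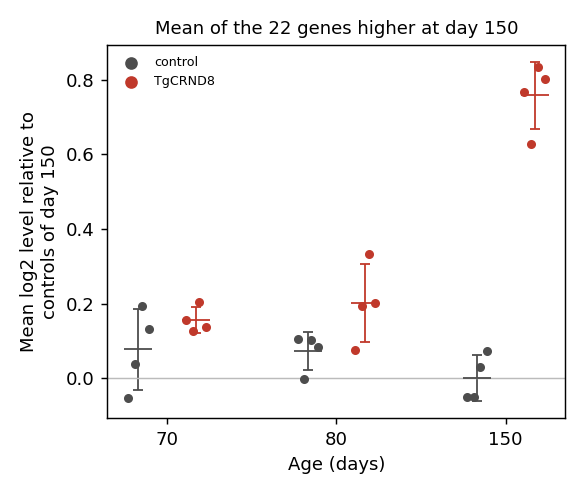
Mean of the 22 genes that passed at day 150, relative to day 150 controls, for each array (4 per group). The day 150 arrays served to pick the genes.

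Taking the 3 ages together, 5 glial genes and Rims1 were higher and Prmt3 was lower in TgCRND8. Gfap rose by 0.61 log2 (standard error 0.0814), Cst7 by 0.58, the perforin-like gene Mpeg1 by 0.44, Vim by 0.38, C1qa by 0.27 and Rims1 by 0.26, averaged over 12 arrays per genotype. The Cst7 mean came from day 150, with differences of 0.07 at day 70 and 0.06 at day 80, and Rims1 differed by 0.35 at day 70 and -0.06 at day 80. Prmt3 fell by 0.59 (standard error 0.0931), the only gene to fall. Tyrobp (0.52; adjusted p = 0.0717 by limma) and Trem2 (0.19) did not pass. By limma with Benjamini-Hochberg adjustment 7 genes passed, with adjusted p = 1.44e-05 for Cst7, 0.000548 for Gfap, 0.00671 for Prmt3 and 0.0478 for Rims1. Median centring left 4 genes, 3 higher and 1 lower. Cst7, Gfap, Mpeg1 and Prmt3 passed in all 24 fits with 1 array left out, and C1qa, Vim and Rims1 in 8, 7 and 3 of them. With the mean of all probe sets of a gene, Prmt3, Vim and Rims1 no longer passed.

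**Figure D4:**
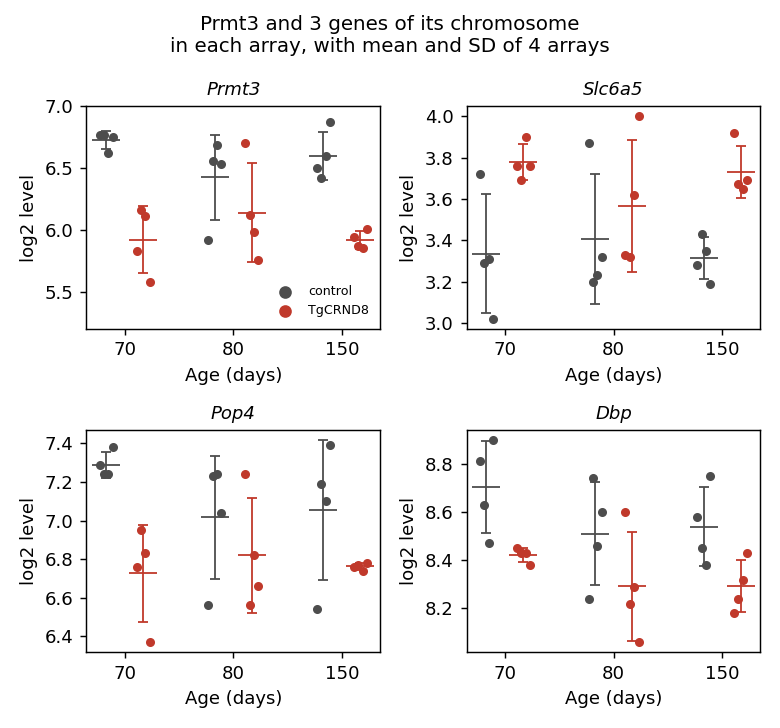
Log2 signal of Prmt3 and of Slc6a5, Pop4 and Dbp on the same chromosome (GRCm38.p6) by genotype and age; dots are arrays, 4 per group.

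For the mean over the 3 ages, 6 gene groups were higher and held with an estimated correlation. The median of each was largest at day 150. It was -0.0021, 0.054 and 0.178 at days 70, 80 and 150 for plaque-associated microglia genes, and 0.081, -0.007 and 0.194 for cholesterol synthesis genes. At day 70, at day 80 and for their mean, 0 lists held with an estimated correlation. Cholesterol synthesis genes were higher for 19 of 20 (median 0.082; 0 passed over all genes and 7 over the list alone by limma, with 574 of all genes at unadjusted p under 0.05). Plaque-associated microglia genes had a median of 0.064, homeostatic microglia 0.083, complement 0.013, antigen presentation 0.047 and reactive astrocytes 0.052. Adjusted p by camera with an estimated correlation was 0.0209, 0.000126, 0.00439, 0.0169, 0.049 and 0.00718 in that order. Oligodendrocyte and myelin genes were lower by a median of 0.088 (adjusted p = 7.22e-07 by camera; adjusted p = 0.0536 with an estimated correlation). Lysosome genes had adjusted p = 3.86e-07 by camera, or adjusted p = 0.106 with an estimated correlation.

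Cst7 and Gfap, markers of glia around plaques, rose more at day 150 than at the earlier ages. Cst7 differed between genotypes by 1.53 log2 more at day 150 than at the mean of days 70 and 80 (standard error 0.129), and Gfap by 1.21 more (standard error 0.173). Tyrobp (1.20), Cd68 (0.90), Ptprc (0.70), C1qc (0.66), Osmr (0.60) and Trem2 (0.64) did not pass. By limma with Benjamini-Hochberg adjustment on all 24 arrays, adjusted p was 1.33e-07 for Cst7, 0.00208 for Gfap, 0.0817 for Tyrobp and 0.404 for Trem2. Plaque-associated microglia genes (median 0.16; adjusted p = 0.000256 by camera with an estimated correlation) and complement genes (median 0.21; 0.0213) also differed more at day 150. Without the dimmest 40% of genes only Gfap was left, since Cst7 was not tested there.

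Between days 70 and 80 no gene passed for a change of the genotype effect: Gfap differed by 0.22 log2 and Cst7 by -0.01 (4 arrays per group; adjusted p = 1 for each by limma with Benjamini-Hochberg adjustment). By limma 0 genes passed and 481 had unadjusted p under 0.05. Camera passed 4 lists, 0 with an estimated correlation; for oligodendrocyte and myelin genes the median was 0.13 (adjusted p = 0.00845 by camera; adjusted p = 0.968 with an estimated correlation).

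In control mice myelin genes were lower at day 150 than at day 70. Mog, coding for a protein of the outer myelin surface, fell by 0.70 log2 (7.18 to 6.49), Ugt8a, the enzyme of galactosylceramide synthesis, by 0.54, the myelin lipid raft gene Mal by 0.49 and the tetraspanin gene Tspan2 by 0.41. For each of these 4 genes all 4 arrays of day 150 lay below all 4 of day 70. The same day 70 controls entered the day 70 genotype difference, the mean of days 70 and 80 and the changes between these ages. Their myelin mean lay 0.128 to 0.225 above that of all arrays, against -0.00143 to 0.104 in day 80 controls. The myelin results of these comparisons are therefore not independent. Of 21 oligodendrocyte and myelin genes 19 were lower (median -0.25): 4 fell, 17 did not pass, and 10 passed over the list alone. Newborn neuron and cell cycle genes were lower for 15 of 19 (median -0.11), among them Sox11 (-0.35), Sox4 (-0.30) and Dcx (-0.08), none of which passed over all genes; by limma over the list alone 4 passed, and 1454 of all genes had unadjusted p under 0.05.

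By limma with Benjamini-Hochberg adjustment, n = 4 per group, 4 genes fell with age in controls and 0 rose, with adjusted p = 0.0165 for Ugt8a and Mal and 0.0409 for Mog and Tspan2. Pbx3 (-0.48; adjusted p = 0.0679 by limma), Gpr17 (-0.63; 0.0721), Dnajc14 (-0.43; 0.0767), Cryab (-0.43; 0.2) and Sox6 (-0.30) did not pass. Camera gave adjusted p = 2.07e-11 for oligodendrocyte and myelin genes and 0.00204 for newborn neuron and cell cycle genes, and adjusted p = 0.0206 for both with an estimated correlation. Cholesterol synthesis genes (18 of 20 lower; adjusted p = 3.1e-08 by camera) had adjusted p = 0.106 with an estimated correlation, and neuropeptide genes (20 of 24 lower; 0.000774) had adjusted p = 0.166 with an estimated correlation. Antigen presentation genes (17 of 19 higher; adjusted p = 0.0213 by camera) and interferon response genes (21 of 28 higher; 0.0464) had adjusted p = 0.386 with an estimated correlation. Lymphocyte genes (12 of 14 higher; 0.035) and meninges and fibroblast genes (15 of 19 higher; 0.0181) had adjusted p = 0.47 with an estimated correlation. The single-gene calls were fragile: 0 genes passed with only the 8 compared arrays in the fit, and 0 with control array number 4 of day 70, number 2 of day 150 or number 4 of day 150 left out. With the Xist level as covariate Ugt8a and Mal passed.

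In TgCRND8 mice the glial genes rose between days 70 and 150. Cst7 rose by 1.52 log2, Gfap by 1.13, Tyrobp by 1.01, Mpeg1 by 0.85, Lyz2 by 0.78, Trem2 by 0.78 and Osmr by 0.75. The transporter genes Abca8a and Slc14a1, the latter for urea, rose by 0.71 and 0.57, and Ctse rose by 0.55; in controls Abca8a differed by 0.46 and Slc14a1 by -0.07 without passing. Col3a1, a collagen gene of fibroblasts, fell by 0.67. By limma with Benjamini-Hochberg adjustment, n = 4 per group, 15 genes rose and 1 fell, with adjusted p = 1.56e-09 for Cst7, 0.000186 for Gfap, 0.018 for Tyrobp, 0.00362 for Trem2 and 0.0468 for Col3a1. With TgCRND8 array number 4 of day 70 left out 8 genes passed, 9 without number 1 of day 70 or number 4 of day 150, and 10 without number 2 of day 70. Cd14 (0.54) passed in 0 of the 8 fits with 1 array left out, Col3a1 in 1 and Ccl3 (0.45) in 2. Ccl3 read 2.81 at day 70 and 3.27 at day 150, below or within the range of the arrays' lower quartiles (3.15 to 3.32). The size of its rise is therefore uncertain.

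The groups that rose with age in TgCRND8 were largely those of immune cells. Plaque-associated microglia genes were higher for 28 of 32 (median 0.16; 7 rose, 25 did not pass), antigen presentation genes for 17 of 19 (median 0.17; Ctss rose, 18 did not pass), and lysosome genes had a median of 0.13 (2 rose, Ctss and Ctsd). Complement genes had a median of 0.076, reactive astrocyte genes 0.092 and cytokine and chemokine genes, of which Ccl3 (0.45) and the receptor gene Cd14 rose, 0.044. Adjusted p by camera with an estimated correlation was 2.01e-06, 0.00124, 0.0168, 0.000433, 0.000433 and 0.0168 in that order. In controls the median was 0.066 for antigen presentation and 0.028 for cytokine and chemokine genes. Cholesterol synthesis genes were lower with age in TgCRND8 for 15 of 20 (median -0.057). Adjusted p by camera was 0.0319 for them, or 0.487 with an estimated correlation. Activity-regulated genes (median 0.13; adjusted p = 9.35e-05 by camera) had adjusted p = 0.24 with an estimated correlation, and glucocorticoid response genes (median 0.12; 9.35e-05) had adjusted p = 0.0636 with an estimated correlation. Myelin genes were lower by a median of 0.085 (adjusted p = 0.00417 by camera; adjusted p = 0.24 with an estimated correlation), with Ugt8a at -0.39 and Mog at -0.37.

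Between days 70 and 80 control mice showed no gene that passed: Commd7 differed by -0.30 log2, Fbxo32 by -0.32, Fgf21 by 0.30, Zfp513 by 0.28 and Atp23 by -0.35 (n = 4 per group; adjusted p = 1 for each by limma with Benjamini-Hochberg adjustment). By limma 0 genes passed and 590 had unadjusted p under 0.05. Camera passed 3 lists, 0 with an estimated correlation. Oligodendrocyte and myelin genes had a median of -0.16 (adjusted p = 3.33e-06 by camera; adjusted p = 0.28 with an estimated correlation) and glucocorticoid response genes 0.12 (0.000672; adjusted p = 0.28 with an estimated correlation).

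Genotype differences over all 18193 genes were not shared between ages beyond what relabelled arrays gave. The correlation of log2 differences was 0.114 between days 70 and 80, -0.0578 between days 70 and 150 and -0.169 between days 80 and 150. Relabelling the genotypes within each age 100 times gave ranges of -0.396 to 0.469, -0.492 to 0.415 and -0.459 to 0.459 (permutation p = 0.663, 0.743 and 0.416).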

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

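The tests of the day 80 arrays numbered 1, of Prmt3 and its chromosome, and of microglial and astrocyte number were chosen after the results were seen, as were the genes and widths used in them.

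For Prmt3 both day 80 arrays numbered 1 lay on the side of the other genotype: TgCRND8 read 6.70 against 5.76 to 6.12 in the other 3, and control 5.92 against 6.53 to 6.69. If the labels had been exchanged, 45 genes of other chromosomes that differed at days 70 and 150 should exchange too: the TgCRND8 array lay at -0.134 and the control at -0.0705, a difference of -0.0639, but both lay nearer the other controls (mean -0.102) than the other TgCRND8 arrays (0.0231). If only the Prmt3 probe set were noisy, nearby genes should not follow. For 3 of 5 genes on the same chromosome (Dbp, Grin2d and Slc6a5) both arrays also lay on the other side (exact binomial p = 0.104), while for Ppfia3 both lay on their own side. Of the other 6 day 80 arrays, 5 lay on their own side for Dbp and for Slc6a5, 3 for Grin2d and only 2 for Ppfia3. Pop4, not among the 5 genes, also lay on the other side. It read 7.24 in the TgCRND8 array against 6.56 to 6.82 in the other TgCRND8 arrays. The control array read 6.56 against 7.04 to 7.24 in the other controls. Neither explanation could be ruled in or out, and the arrays stayed under their labels.

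The lower Prmt3 signal in TgCRND8 could come from a sequence difference under 1 probe set or from a chromosome stretch inherited with the transgene. Other Prmt3 probe sets, all dimmer than the median probe set, had a smallest unadjusted p of 0.0036 by limma: it was lower by 0.19 log2 and a second by 0.18, which goes against a difference under only 1 probe set, while 2 others differed by 0.017 and 0.029. At such low signal they do not exclude it. Among stretches of 200 measured genes the best held Prmt3, Pop4, Slc6a5, Dbp and Zfp975 at small p, and 4 of 100 relabellings held as many; for 400 genes it was 5 of 100, and for 100 genes the best stretch did not hold Prmt3 and 14 of 100 did as well. Without the day 80 arrays numbered 1, Pop4, Slc6a5 and Dbp passed for the mean over ages, but those arrays were picked by their Prmt3 values. A linked stretch therefore remains possible and unproven, and whether Prmt3 responds to the transgene itself cannot be told.

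The 22 genes higher at day 150 might reflect more microglia or astrocytes rather than higher levels per cell. The 11 bright homeostatic microglia genes were higher by 0.152 log2 (95% interval 0.0442 to 0.26), against 0.776 (0.657 to 0.894) for the 13 microglial genes that passed. The 20 bright astrocyte genes differed by 0.0132 (-0.0743 to 0.101), against 1.08 (0.825 to 1.33) for Gfap and Vim. Picking genes for their rise inflates the larger means, so these contrasts alone do not decide. Over whole lists the medians lay closer: 0.178 for plaque-associated and 0.118 for homeostatic microglia genes, and 0.0477 for reactive astrocyte and -0.002 for astrocyte genes. Gfap, a gene of the fixed set, rose by 1.42 (standard error 0.141), far above 0.101. For that gene this argues against more astrocytes at unchanged levels per cell. Tyrobp, also of the fixed set, rose by 1.31 (standard error 0.182), above 0.26. Homeostatic genes may themselves fall in activated cells, so a rise in microglial number stays possible as a cause of the microglial genes.

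The genotype effect of 2 genes differed by age: Gfap by 1.21 log2 and Cst7 by 1.53 more at day 150 than before. Besides these, 3 probe sets without a single gene name were higher at day 150, and 32 of 45037 probe sets passed in all by limma.

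In 42 genes examined group by group, 15 of 252 groups held 1 array set apart from the other 3 by a Dixon gap test, where 12.6 are expected by chance. In controls these were Apoe in number 2 of day 150 (12.02; others 12.16 to 12.19), Cd68 in number 3 of day 150 (4.16; 4.52 to 4.59), C1qa in number 3 of day 80 (7.25; 7.37 to 7.39), Ccl3 in number 4 of day 80 (3.04; 2.88 to 2.90) and Mal in number 1 of day 80 (9.33; 9.22 to 9.23). At day 70 they were Clec7a in number 3 (3.42; 3.05 to 3.09), Ctss in number 1 (8.61; 8.91 to 8.93), Prmt3 in number 3 (6.62; 6.75 to 6.77) and Vim in number 4 (6.96; 6.43 to 6.51). In TgCRND8 they were C1qa (7.77; 7.89), Cd9 (8.20; 8.45 to 8.49) and Col3a1 (4.60; 4.18 to 4.23) in number 2 of day 150, and Cd14 in number 1 of day 80 (4.47; 4.82 to 4.88). At day 70 they were Mpeg1 in number 3 (4.90; 5.15 to 5.19) and Ugt8a in number 4 (8.41; 8.64). No array was left out for these gaps.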

How the results depend on the processing

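Leaving out the day 80 arrays numbered 1, the first principal component as covariate and the other forms of the mean of the 22 genes were chosen after the results were seen; the other settings were fixed before. Of 1050 refits of the 51 gene results that passed, 846 kept the call, 204 lost it and 0 turned direction. Small differences that had not passed, such as Gfap at day 70 (-0.0464 to 0.214 with 1 array left out), did turn.

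With array weights 35 genes passed at day 150, 8 for age in controls and 27 for age in TgCRND8. With the first principal component as covariate 13 passed for the mean over ages, 7 for the change at day 150, 9 for age in controls and 25 for age in TgCRND8. Median centring gave 4 for the mean over ages and 7 for age in controls; quantile normalization gave 2 for age in controls. The cause was not tested.

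Without the dimmest 40% of genes 1 gene passed for the change at day 150 and 9 for age in TgCRND8, since dim genes such as Cst7 were no longer tested. Taking the mean of all probe sets left 9 for age in TgCRND8, and testing all probe sets gave 5 for the change at day 150 and 2 for age in controls. With Xist as covariate 2 passed for age in controls, and with only the arrays compared 0 did. At an adjusted p under 0.10 by limma 11 passed for the mean over ages and 7 for age in controls. The cause was not tested.

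Without both day 80 arrays numbered 1, Prmt3 made 1 gene pass at day 70 and 1 for the mean of days 70 and 80, 11 passed for the mean over ages, 5 lists passed at day 80, and the day 80 difference in the mean of the 22 genes was 0.181 (exact permutation p = 0.1, the smallest possible with 3 against 3). Gained for the mean over ages were Fdft1 (0.254), Pop4 (-0.446), Slc6a5 (0.42) and Dbp (-0.314). Pop4, Slc6a5 and Dbp lie with Prmt3 in the best stretch of 200 measured genes. The arrays left out were singled out by their Prmt3 values, so the gain for Prmt3 does not count in favour of it. The gains for genes of its stretch are not independent of that choice. The cause was not tested.

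Lists that passed by camera with an estimated correlation numbered 0 at day 70, 0 at day 80, 6 at day 150, 6 for the mean over ages, 2 for age in controls and 6 for age in TgCRND8.

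The labels do not say that arrays of 1 replicate number belong together. Taking the number as a block gave 31 genes at day 150, 10 for the mean over ages, 4 for the change at day 150, 7 for age in controls and 21 for age in TgCRND8. Residuals of arrays sharing number 1, 2, 3 or 4 correlated by 0.227, 0.0059, 0.261 and -0.0356 on average against -0.0382 for different numbers, and 12 of 24 arrays were closest to one of their own number, so numbers 1 and 3 may mark a shared step; the block was not used because no source states it.

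Leaving out each array in turn gave 0 to 0 genes at day 70, 0 to 2 at day 80, 12 to 20 at day 150, 4 to 10 for the mean over ages, 0 to 1 for the mean of days 70 and 80, 2 to 3 for the change at day 150, 0 to 0 for the change at day 80, 0 to 3 for age in controls, 8 to 14 for age in TgCRND8 and 0 to 0 for days 70 and 80 in controls. For the mean over ages 4 genes passed without any 1 of 13 arrays: controls numbered 1 and 2 of day 70, 2 and 4 of day 80, 1 and 2 of day 150, and TgCRND8 numbered 2 and 3 of day 70, 2 and 3 of day 80, and 1, 3 and 4 of day 150. For age in controls 1 gene passed without control number 1 of day 70 or 3 of day 150, and 2 without number 3 of day 70. Lists that passed ranged over 6 to 11 at day 70, 0 to 7 at day 80, 10 to 13 at day 150, 13 to 18 for the mean over ages, 6 to 18 for age in controls and 12 to 18 for age in TgCRND8. At day 80, 7 lists passed without TgCRND8 number 1 or control number 3, 4 without control number 4, 2 without control number 1 or TgCRND8 number 2 or 4, and 0 without TgCRND8 number 3. For age in controls 18 lists passed without number 3 of day 70, and 6 without number 4 of day 70 or number 1 of day 150. The mean of the 22 genes differed by 0.0345 to 0.117 at day 70 and 0.0842 to 0.17 at day 80. The cause was not tested.

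Pseudocount alternatives were not run because the values were already log2.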

Other observations

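The splits for day 70, day 80, their mean, the change between days 70 and 80, and days 70 and 80 in controls were described after the results were seen, the other splits before, and the groups in the next paragraph were picked after their values were seen.

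Besides the groups that passed at day 150, several others did not pass. Oxidative phosphorylation genes had a median of -0.026 over 40 genes (12 higher, 28 lower; adjusted p = 0.268 by camera), with Cox4i1 at 0.02, and proteasome genes -0.00097 over 27 (adjusted p = 0.769 by camera). Interferon response genes, which can accompany microglial activation, had a median of 0.016 over 28 genes (adjusted p = 0.582 by camera), with Ifit3 at -0.0016. Presynaptic genes had a median of 0.04 over 21 genes (adjusted p = 0.188 by camera) beside the difference in Rims1. The limits are those of 4 arrays per group.

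Pituitary hormone genes varied between single TgCRND8 forebrains at each age: the mean of the 7 list genes was 1.94 log2 above the mean of all arrays in number 4 of day 150, 1.04 in number 1 of day 70 and 0.735 in number 2 of day 80. At day 150 Prl was higher by 1.33 (SD 3.4 in TgCRND8). At day 70 Prl was higher by 1.23 log2 (4.44 with SD 1.1 against 3.21 with SD 0.16, n = 4 per group), Gh by 0.97 and Pomc by 0.95, without passing. The list at day 70 (6 of 7 higher) had adjusted p = 0.0236 by camera, or adjusted p = 0.643 with an estimated correlation.

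At day 150 the real grouping gave 22 genes of glia and Rims1, and 1 of 35 splits, the real one itself, gave as many. The highest other gave 1. A share of 1 in 35 is the smallest possible, and several comparisons were examined this way without adjustment. Chance is therefore made unlikely for this count but not excluded. For the mean over ages, with Gfap, Cst7 and Prmt3 among 7 genes, 1 of 100 labellings, the real one itself, gave as many (highest other 3). Chance is made unlikely for that count but not excluded, and the labellings do not address single genes such as Prmt3. For the change at day 150, with Cst7 and Gfap as the 2 genes, 5 of 100 gave as many and the highest other was 14, so chance cannot be excluded for the count.

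For age in controls the 4 myelin genes were reached by 1 of 35 splits, the real one (highest other 0). For age in TgCRND8 the 16 genes around Cst7 and Gfap were also reached by 1 of 35 (highest other 0). This is the smallest share possible, so chance is not excluded for either count. In controls the count fell to 0 with only the 8 compared arrays in the fit or with any 1 of 3 arrays left out. Of the 4 genes, 0 passed in all 8 fits with 1 array left out. Where 0 genes passed, every split necessarily gave as many, which says nothing about chance: 35 of 35 at day 70 (highest other 0), 35 of 35 at day 80 (highest other 915), 100 of 100 for the mean of days 70 and 80 (581), 100 of 100 for the change between days 70 and 80 (1042) and 35 of 35 for days 70 and 80 in controls (18). The 915 genes of day 80 belong to a split of TgCRND8 1 and 4 and control 1 and 2 from the rest. It follows the largest component of all arrays (20.8% of variance), along which genotypes were not separated at any age (exact permutation p = 0.6 to 0.857), and points to a structure of the samples. On it all arrays numbered 1 were negative (-12.9 to -4.32) and all numbered 3 positive (0.993 to 18.8). Arrays numbered 2 and 4 lay on both sides. What a replicate number stands for is not stated in the labels.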
